A study of Mus musculus with 13 samples.

How the data were processed

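RNA was extracted from 13 formalin-fixed, paraffin-embedded mouse prostate tumours and converted to biotin-labelled single-stranded cDNA from 12 ng of total RNA for a whole-transcript Affymetrix array, per the labels' protocols. The authors deposited 1 table of log2 signals for 65956 probe sets, made with RMA (background correction, normalization and summary of probes into probe sets), per the submitters' processing notes. The RMA software, its version, its background settings and the probe-set library are not given in the sources used here. The deposited log2 values ran from 1.62 to 21.41, and 603 probe sets exceeded 16, the log2 range of a 16-bit scanner, on at least 1 array. A step that stretches the scale beyond plain RMA is therefore possible, and log2 differences are given on the deposited scale, which may overstate the fold of bright genes. Columns were assigned to samples by their identifiers, and samples to groups and replicate numbers by their titles. No detection calls or array dates were used here, so no measured background level was at hand, olfactory receptor genes served as a guide to it, and batches could not be tested.

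Probe sets were named through the platform's annotation table: 32814 of the 65956 were listed with a gene, 30638 with 1 symbol and 2176 with several, and 33142 were not listed and stay unnamed. A RefSeq gene table of mouse assembly GRCm38 held the gene identifiers of 22596 of them, with 0 changed symbols, and was used for names, synonyms and gene types only. No genome build is named for the array design, so no coordinates are given. Probe sets with 1 symbol gave 30176 genes; for the 354 genes with several probe sets, the one with the highest mean over all arrays stood for the gene. No filter on dim genes was applied.

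Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend or robust options) on the deposited log2 values, with all 13 arrays and 3 groups in 1 fit, which leaves 10 residual degrees of freedom. The comparisons were early carcinoma against PADC, late carcinoma against PADC and late against early carcinoma. P-values were two-sided and adjusted by Benjamini-Hochberg over the 30176 genes within each comparison, and a gene was called at an adjusted p under 0.05. Stk11 was also tested with exact two-sided permutation of the arrays. Array numbers 1 to 4 recur in each group, but no label says that they pair the samples.

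Before the data were examined, 46 gene lists were fixed for cell types of the prostate and neighbouring tissue, immune cells, hormone response, metabolism and signalling; 45 had at least 5 measured members. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated from the data, on ranks, and with fry (statmod 1.5.0). Genes are named in the text by a rule fixed at the same time: the targeted genes, the 8 largest rises and 8 largest falls among called genes with values that do not overlap between the groups, leaving out unnamed and predicted genes, and up to 4 members of each list with the smallest p.

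Alternatives were cyclic loess, quantile normalization or median centring of the deposited values, filters on dim genes, the mean of a gene's probe sets, all probe sets, trended and robust variance, array weights, fits of only the groups compared, a replicate block, leaving out each array in turn, a plain test per gene and a 2-fold threshold. Added after the data were seen were the 5th percentile of each array as a covariate, leaving out early carcinoma replicate 3 and PADC replicate 2 together, and protein-coding genes only. The fit was tested on simulated data with 200 of 30176 genes changed. For early carcinoma against PADC it recovered 42% of changes of 0.5 log2 units, 82% of changes of 1 and 98% of changes of 2; for late carcinoma against PADC 42%, 84% and 92%; for late against early carcinoma 40%, 86% and 92%. Camera recovered the moved list in late carcinoma against PADC and called 0 of 20 unmoved lists. The simulated genes were independent and the lists random, so this does not check camera's p-values where the genes of a list are correlated. Figures were drawn with matplotlib 3.10.9.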

Results

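Gene expression was measured in 13 mouse prostate tumours kept as formalin-fixed, paraffin-embedded (FFPE) tissue, each on a whole-transcript Affymetrix array. The tumours came from mice with prostate alleles that the labels write as Ptenpc and Lkb1pc. Pten encodes a lipid phosphatase that opposes phosphoinositide 3-kinase, and Lkb1 is another name of Stk11, which encodes a kinase that activates AMPK and related kinases. Carcinomas of Ptenpc+/- Lkb1pc-/- mice were taken at an early stage (6 months, n = 4) and a late stage (10 months, n = 4). Prostate adenocarcinomas (PADC, n = 5) came from Ptenpc-/- Lkb1pc+/+ mice, whose age the labels do not state. The design sets both carcinoma stages against PADC, so genotype, age and histology differ together in those comparisons. Each label names tissue from a mouse, but no label says that the mice of a group were separate animals, so the p-values measure the spread between these samples.

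Signals are given as deposited log2 units for 30176 genes, and the number of arrays limits the precision of each value. Some signals exceed the log2 range of a 16-bit scanner, so differences of bright genes hold on the deposited scale only. The 5th percentile of the genes was 3.90 ± 0.10 (SD, n = 4) in the early carcinomas, 3.83 ± 0.06 (SD, n = 5) in PADC and 3.73 ± 0.03 (SD, n = 4) in the late carcinomas. The 95th percentile was 8.96 ± 0.16 in the early carcinomas, 8.74 ± 0.21 in PADC and 9.54 ± 0.15 in the late carcinomas, so the late arrays spanned the widest range. Arrays of a group correlated across genes with r from 0.968 to 0.985 in the early carcinomas, 0.989 to 0.992 in the late carcinomas and 0.97 to 0.992 in PADC, where genes are not independent replicates. No pair of arrays held the same values.

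**Figure D1:**
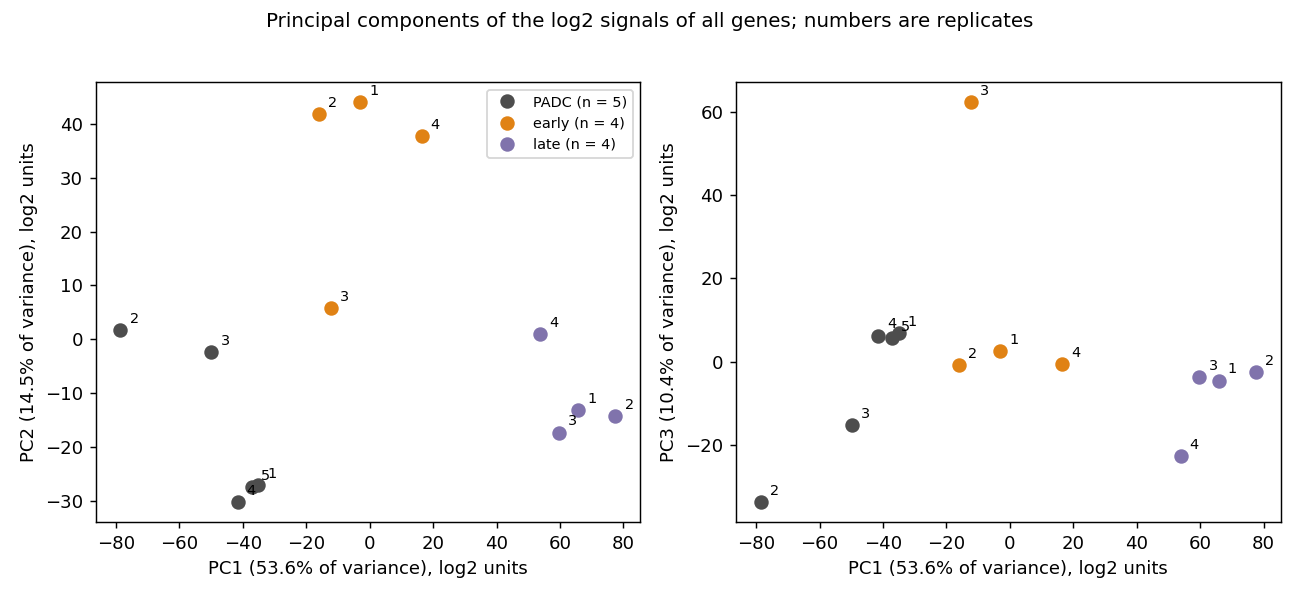
Principal components of the log2 signals of 30176 genes, one point per array, coloured by group (5 PADC, 4 early and 4 late carcinomas) and numbered by replicate; axes are scores in log2 units with the percent of variance. The first component (53.6% of the variance) separates PADC (-78.5 to -35.1), the early (-15.9 to 16.4) and the late carcinomas (53.8 to 77.5). Early carcinoma replicate 3 lies apart from the other early arrays on the second (14.5%) and the third (10.4%). On the second, PADC replicates 1, 4 and 5 (-30.3 to -27.2) also lie apart from PADC replicates 2 and 3 (1.8 and -2.4).

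The targeted gene Stk11 was measured first, since its level checks the labels. Stk11 was 7.28 ± 0.08 (SD, n = 5) in PADC, 6.71 ± 0.35 (SD, n = 4) in the early carcinomas and 6.59 ± 0.06 (SD, n = 4) in the late carcinomas. It was lower than in PADC in the late carcinomas by a log2 difference of -0.69 (limma adjusted p = 0.00211; exact two-sided permutation p = 0.00794, the smallest that 126 regroupings can give). In the early carcinomas the log2 difference was -0.57 (limma adjusted p = 0.0184; exact two-sided permutation p = 0.0159). The array labelled early carcinoma replicate 3 read 7.21 for Stk11, inside the PADC range of 7.18 to 7.39, whereas the other early arrays read 6.40, 6.69 and 6.55. The early call was lost without early carcinoma replicate 1 (log2 difference -0.47, limma adjusted p = 0.0523) or replicate 4 (-0.52, adjusted p = 0.0589). Late and early carcinomas did not differ in Stk11 beyond the spread (log2 difference -0.12, limma adjusted p = 0.523; exact two-sided permutation p = 0.714), and this difference was 0.05 without early carcinoma replicate 3. Stk11 is on 1 probe set, and whether it lies in the deleted part is not given in the sources used here; stroma in the tissue would keep the gene. Pten was not analysed here, because no probe set is listed under it alone.

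**Figure D2:**
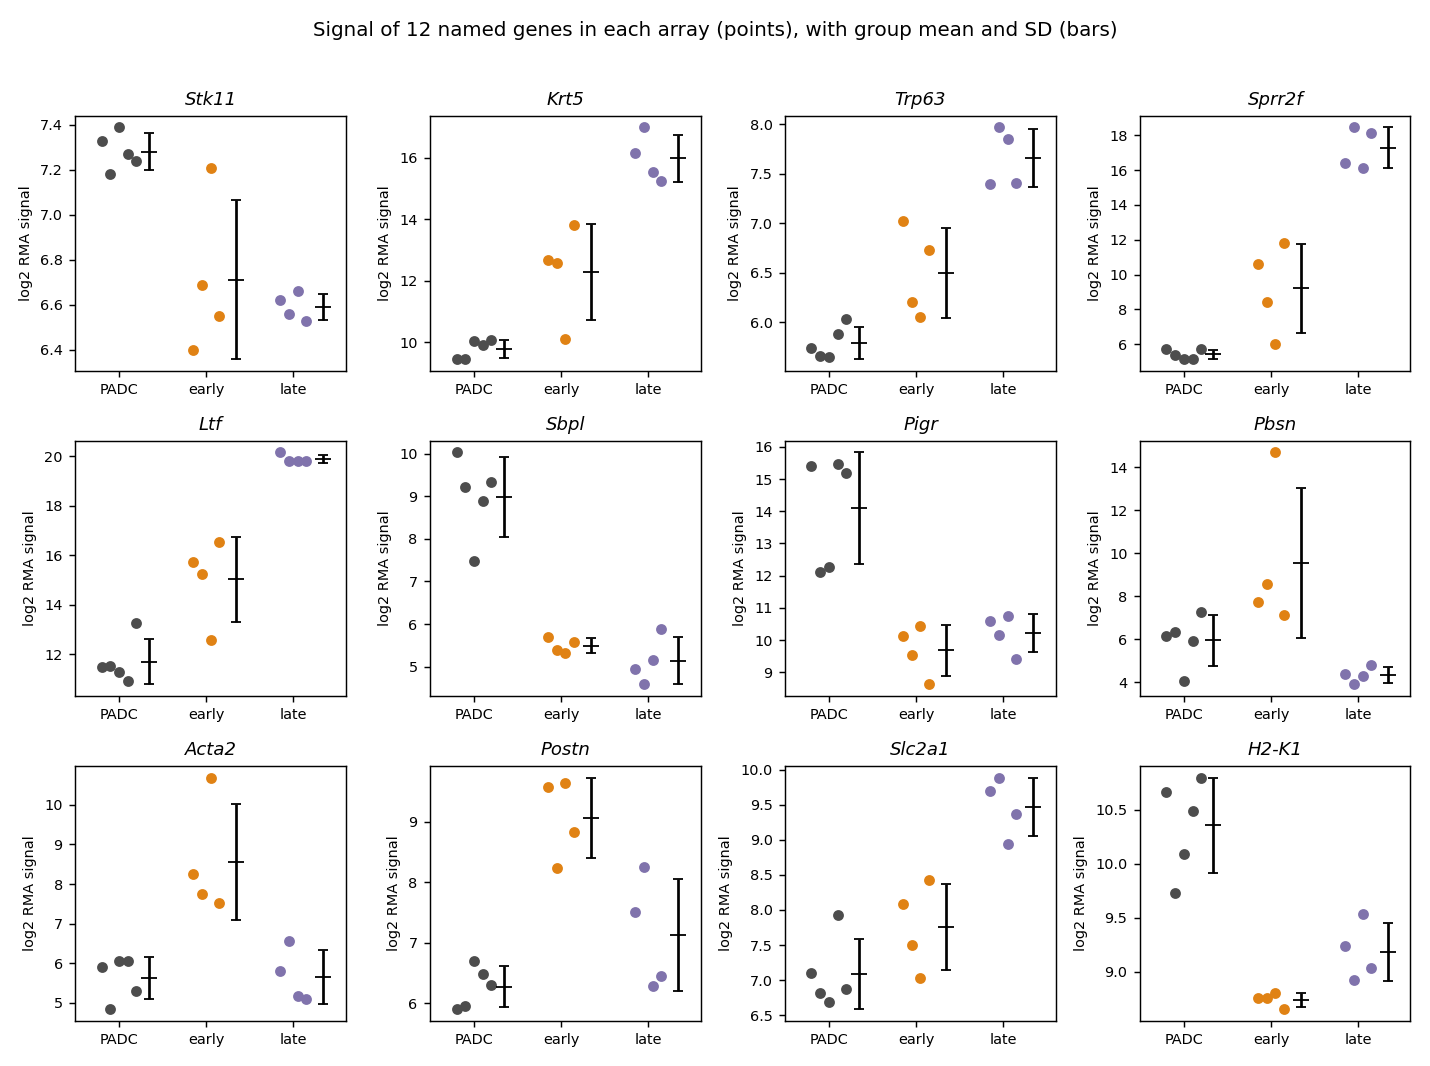
Signal of 12 named genes on each array (points, log2 RMA signal on the vertical axis, with a scale of its own in each panel) for PADC (n = 5), early (n = 4) and late carcinomas (n = 4); the bar beside each group is its mean and SD. Krt5 and Sprr2f are highest in the late carcinomas (means of 15.97 and 17.29), Sbpl and Pigr are highest in PADC (8.99 and 14.09), and Postn and Acta2 are highest in the early carcinomas (9.06 and 8.55).

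Early carcinomas were compared with PADC to ask how tumours labelled Lkb1pc-/- differ at their early stage from tumours labelled Ptenpc-/-. The secretoglobin Scgb1b20 was 11.88 ± 2.92 (SD, n = 4) in the early carcinomas and 5.79 ± 0.58 (SD, n = 5) in PADC, a rise of 6.09 log2 units (SE 1.07, limma adjusted p = 0.00590). Another secretoglobin, Scgb2b24, rose by 4.82 (SE 0.783, adjusted p = 0.00423), the beta-defensin Defb14, an antimicrobial peptide, by 4.78 (SE 0.930, adjusted p = 0.00938) and Sprr2d, a protein of the cornified envelope of squamous cells, by 4.42 (SE 0.865, adjusted p = 0.00960). The gasdermins Gsdmc2 and Gsdmc3 fell by 5.98 (SE 1.06, adjusted p = 0.00611) and fell by 5.71 (SE 1.0, adjusted p = 0.00589). Spink5, an inhibitor of serine proteases of epithelia, fell by 4.88 (SE 0.945, adjusted p = 0.00924), and Pigr, the receptor that carries antibodies across epithelium, fell by 4.41 (SE 0.746, adjusted p = 0.00502). Without the array labelled early carcinoma replicate 3 the rises of Scgb1b20 and Scgb2b24 were 4.67 and 3.65. Scgb2b24 was 3.34 in PADC, below olfactory receptor genes (4.29), so the size of its rise is uncertain. Of 30176 genes, 2140 rose and 1027 fell (limma, Benjamini-Hochberg); 461 of the rises and 167 of the falls were 2-fold or more on the deposited scale.

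The number of genes called between early carcinomas and PADC rested on single arrays. It was 3167 with all arrays, 6405 without the array labelled early carcinoma replicate 3, 1588, 1968 and 1529 without early carcinoma replicates 1, 2 and 4, and 2108 without PADC replicate 5. Of the calls, 67.6% were rises, against 55.8% after cyclic loess, 54.1% with each array centred on its median and 48.0% after quantile normalization. Among the 10055 dimmest genes 635 rose and 140 fell, and among the 10060 brightest 910 rose and 576 fell. Of 1082 olfactory receptor genes 75 rose and 19 fell (median 0.09). A difference in background level could therefore account for part of the rises of dim genes.

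Most muscle genes measured, and a few matrix genes, were higher in the early carcinomas. In the smooth muscle list, 14 of 18 measured members rose over all genes tested and 17 adjusted over the list alone, with 0 falling. Acta2, the actin of smooth muscle, rose by 2.92 log2 units (SE 0.573, limma adjusted p = 0.00969), and Tagln, which binds actin in the same cells, rose by 1.26 (SE 0.258, adjusted p = 0.0118). Acta2 read 10.69 on the array labelled early carcinoma replicate 3 and 7.52 to 8.25 on the other early arrays, so the size of its rise rests partly on that array. In the skeletal muscle list 13 of 19 rose over all genes tested and 14 adjusted over the list alone. Ttn, the giant spring protein of the sarcomere, rose by 1.82 (SE 0.246, adjusted p = 0.00199), and the fast myosin Myh1 rose by 1.20 (SE 0.173, adjusted p = 0.00245). In PADC Ttn (4.19) and Myh1 (4.29) stood no higher than olfactory receptor genes (4.29), so the sizes of these rises are uncertain. Both lists passed camera at its preset correlation (adjusted p = 1.14e-08 and 1.11e-08), and with an estimated correlation neither did (adjusted p = 0.510 for each). Of the fibroblasts and extracellular matrix list, 4 of 23 rose over all genes tested and 5 adjusted over the list alone (camera adjusted p = 6.32e-04; adjusted p = 0.597 with an estimated correlation). Postn, a matrix protein, rose by 2.80 (SE 0.403, adjusted p = 0.00241). The number of smooth muscle members that rose was 6 without early carcinoma replicate 1, that of skeletal muscle was at least 11 with any array left out, and that of fibroblast genes was 7 without early carcinoma replicate 3.

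Secretory genes of the male tract moved both ways. Of the seminal vesicle secretory genes, 7 of 12 rose over all genes tested and 9 adjusted over the list alone (camera adjusted p = 3.01e-05; adjusted p = 0.510 with an estimated correlation). Sva rose by 2.98 (SE 0.40, limma adjusted p = 0.00197) and Svs6 by 2.70 (SE 0.404, adjusted p = 0.00294); their PADC means (3.14 and 3.51) lay below olfactory receptor genes (4.29), so these sizes are uncertain. Of the mouse prostate secretory genes, 4 of 20 rose and 6 fell over all genes tested, and 5 rose and 9 fell adjusted over the list alone (camera down, adjusted p = 0.00418; adjusted p = 0.597 with an estimated correlation). The call of this list was also lost with camera on ranks (adjusted p = 0.0555), with fry (0.15) and with the 5th percentile of each array as a covariate (0.582). Of its members Sbpl, a relative of the spermine-binding protein of the ventral prostate, fell by 3.49 (SE 0.409, adjusted p = 0.00112), and the prostate transglutaminase Tgm4 rose by 4.57 (SE 1.14, adjusted p = 0.0268). The number of prostate secretory genes that rose was 1 without early carcinoma replicate 2. Without the array labelled early carcinoma replicate 3 the Tgm4 rise was 2.93, and its PADC mean (4.16) lay below that of olfactory receptor genes (4.29), so the size of the rise is uncertain. The Tgm4 call was lost without early carcinoma replicate 2 (4.72, adjusted p = 0.0533), PADC replicate 1 (4.57, adjusted p = 0.0506) or PADC replicate 4 (4.51, adjusted p = 0.0532), and with only the groups compared (adjusted p = 0.0759).

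Some squamous and proliferation genes were higher in the early carcinomas, and how many depended on single arrays. In the list of squamous differentiation and cornified envelope genes, 10 of 39 rose over all genes tested and 16 adjusted over the list alone, with 0 falling (camera adjusted p = 2.01e-06; adjusted p = 0.597 with an estimated correlation). Sprr1a, a cornified envelope protein, rose by 1.91 (SE 0.424, limma adjusted p = 0.0171), a call lost with only the groups compared (1.91, adjusted p = 0.0515). The number that rose was 24 without early carcinoma replicate 3 and 3 without replicate 4. In the cell cycle and mitosis list, 19 of 41 rose over all genes tested and 31 adjusted over the list alone, with 0 falling (camera adjusted p = 1.37e-11; adjusted p = 0.597 with an estimated correlation). Ube2c, which marks mitotic proteins for degradation, rose by 1.28 (SE 0.156, adjusted p = 0.00123), and the S-phase cyclin Ccna2 rose by 1.10 (SE 0.161, adjusted p = 0.00249). That number was 32 without early carcinoma replicate 3 and 7 without replicate 2. Of the basal epithelium list, 6 of 18 rose over all genes tested and 10 adjusted over the list alone (camera adjusted p = 0.00162; adjusted p = 0.597 with an estimated correlation), 11 without early carcinoma replicate 3 and 0 without replicate 4. The basal keratin Krt5 rose by 2.5 (SE 0.593, adjusted p = 0.0225). It read 10.1 on the array labelled early carcinoma replicate 3 and 12.59 to 13.81 on the other early arrays, so that array lowers the size of the rise. The Krt5 call was lost without early carcinoma replicate 1 (2.38, adjusted p = 0.0631), replicate 2 (2.40, 0.0562) or replicate 4 (2.0, 0.0631). It was also lost after cyclic loess (2.11, adjusted p = 0.0529), with only the groups compared (0.0513) and with the 5th percentile of each array as a covariate (1.98, 0.0638).

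Some interferon and antigen presentation genes were lower in the early carcinomas than in PADC. Of the interferon response list, 13 of 24 fell over all genes tested and 17 adjusted over the list alone, with 0 rising (camera adjusted p = 1.53e-14; adjusted p = 0.510 with an estimated correlation). Oas2, an interferon-induced sensor of double-stranded RNA, fell by 3.40 (SE 0.552, limma adjusted p = 0.00420), and the antiviral GTPase Mx2 fell by 1.03 (SE 0.118, adjusted p = 0.00103). Of the antigen presentation list, 5 of 15 fell over all genes tested and 5 adjusted over the list alone (camera adjusted p = 3.88e-06; adjusted p = 0.510 with an estimated correlation). The class I genes H2-K1 and H2-Q4 fell by 1.62 (SE 0.196, adjusted p = 0.00119) and fell by 1.52 (SE 0.129, adjusted p = 3.78e-04). The number of interferon genes that fell lay between 10 and 14 with any array left out, and that of antigen presentation genes was 3 without early carcinoma replicate 1. Tnf, an inflammatory cytokine, fell by 1.34 (SE 0.132, adjusted p = 7.58e-04). In its list, NF-kB and inflammatory cytokines, 2 of 26 rose and 4 fell over all genes tested, and 2 rose and 6 fell adjusted over the list alone (camera down, adjusted p = 0.00375; adjusted p = 0.597 with an estimated correlation). Without early carcinoma replicate 1, 0 members of that list rose. Its call was lost without early carcinoma replicate 3 (camera adjusted p = 0.120), without it and PADC replicate 2 (0.0815) and with fry (0.0671), and its median (-0.09) and mean (0.02) differed in sign.

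Of the 45 lists with at least 5 measured members, 17 passed camera between early carcinomas and PADC, 11 higher and 6 lower, 0 of them with an estimated correlation (smallest adjusted p = 0.510). Fry, which tests whether members move one way on balance, called 18, of which 16 were higher and 2 lower. Only 12 of these were among camera's 17 in the same direction. Of the remaining lists, cholesterol synthesis had 6 of 18 rising over all genes tested and 9 adjusted over the list alone, and ribosomal proteins had 4 of 14 and 10 (camera adjusted p = 6.77e-04 and 3.51e-04; adjusted p = 0.597 for both with an estimated correlation). The call of the ribosomal list was also lost with early carcinoma replicate 3 and PADC replicate 2 both left out (adjusted p = 0.0600). The cholesterol genes that rose numbered 1 without early carcinoma replicate 2. The hypoxia response and glycolysis lists had 0 members past the threshold. The oxidative phosphorylation list passed camera at its preset correlation, a call lost in 4 of 22 alternative settings. In addition, 706 of the rises were pseudogenes, whose probes share sequence with the parent genes, so their own levels are uncertain. The same holds for near-identical family members such as the gasdermins, secretoglobins, Sprr2 genes and H2 genes.

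Late carcinomas were compared with PADC to ask how the advanced stage of tumours labelled Lkb1pc-/- differs from tumours labelled Ptenpc-/-. Sprr2f, a protein of the cornified envelope, was 17.29 ± 1.18 (SD, n = 4) in the late carcinomas and 5.42 ± 0.27 (SD, n = 5) in PADC, a rise of 11.87 log2 units (SE 0.945, limma adjusted p = 1.69e-05). Defb14 rose by 10.70 (SE 0.930, adjusted p = 2.40e-05), Ppbp, a chemokine that attracts neutrophils, by 9.35 (SE 0.946, adjusted p = 5.62e-05) and Ltf, the iron-binding protein lactoferrin, by 8.2 (SE 0.673, adjusted p = 1.79e-05). Ltf stood at 19.90 ± 0.17 (SD, n = 4) in the late carcinomas. Genes of PADC that fell included Cdcp3 by a log2 difference of -4.56 (SE 0.722, adjusted p = 7.35e-04), the ion transporter Slc12a2 with -4.43 (SE 0.857, adjusted p = 0.00268), Pigr with -3.87 (SE 0.746, adjusted p = 0.00260) and the glycosyltransferase B4galnt2 with -3.84 (SE 0.575, adjusted p = 5.17e-04). Of 30176 genes, 4366 rose and 3400 fell (limma, Benjamini-Hochberg), and 1661 of the rises and 379 of the falls were 2-fold or more on the deposited scale. Of the 7766 calls, 56.2% were rises, against 54.0% after cyclic loess, 52.6% after quantile normalization and 79.1% with each array centred on its median. Among the 10055 dimmest genes 100 rose and 837 fell, and among the 10060 brightest 3563 rose and 1031 fell. Of 1082 olfactory receptor genes 4 rose and 93 fell (median -0.14). A difference in background level could therefore account for part of the falls of dim genes.

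Most squamous and basal genes measured rose in the late carcinomas. In the list of squamous differentiation and cornified envelope genes, 27 of 39 rose over all genes tested and 29 adjusted over the list alone, with 0 and 1 falling (camera adjusted p = 2.46e-13; adjusted p = 0.252 with an estimated correlation). Ly6d, a surface protein of stratified epithelium, rose by 7.58 (SE 1.01, limma adjusted p = 2.49e-04), and the desmosomal cadherin Dsc3 rose by 2.41 (SE 0.256, adjusted p = 7.10e-05). Of the basal epithelium list, 13 of 18 rose and 1 fell over all genes tested, and 15 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.23e-08; adjusted p = 0.252 with an estimated correlation). Krt5 rose by 6.19 (SE 0.593, adjusted p = 4.15e-05), Trp63, the transcription factor that maintains basal cells, by 1.87 (SE 0.194, adjusted p = 6.24e-05) and the alarmin cytokine Il33 by 5.14 (SE 0.556, adjusted p = 7.81e-05). Of the urothelium list, 5 of 10 rose over all genes tested and 5 adjusted over the list alone (camera adjusted p = 0.00445; adjusted p = 0.262 with an estimated correlation), among them Psca, a surface antigen of prostate and bladder epithelium, by 4.24 (SE 0.468, adjusted p = 8.86e-05).

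Most genes of energy metabolism measured rose too. Of the hypoxia response list, 16 of 22 rose over all genes tested and 17 adjusted over the list alone, with 0 falling (camera adjusted p = 1.52e-09; adjusted p = 0.252 with an estimated correlation). The glucose transporter Slc2a1 rose by 2.39 (SE 0.314, limma adjusted p = 2.32e-04), and Ero1a, an oxidase of the endoplasmic reticulum, rose by 2.54 (SE 0.313, adjusted p = 1.58e-04). Of the glycolysis list, 13 of 18 rose over all genes tested and 13 adjusted over the list alone (camera adjusted p = 2.34e-07; adjusted p = 0.257 with an estimated correlation). Pgk1, a kinase of glycolysis, rose by 2.75 (SE 0.361, adjusted p = 2.31e-04). In the oxidative phosphorylation list, 27 of 37 rose over all genes tested and 33 adjusted over the list alone, with 0 falling (camera adjusted p = 3.37e-14; adjusted p = 0.252 with an estimated correlation). The cytochrome oxidase subunit Cox5a rose by 1.24 (SE 0.158, adjusted p = 1.93e-04). Of the ribosomal proteins, 14 of 14 rose over all genes tested and 14 adjusted over the list alone (camera adjusted p = 4.03e-12; adjusted p = 0.252 with an estimated correlation). Rpl8 rose by 2.69 (SE 0.317, adjusted p = 1.25e-04), but the number of ribosomal proteins that rose was 9 after cyclic loess and 8 after quantile normalization. In the same comparison 53 of 62 ribosomal RNA genes fell and 0 rose, and 283 of 915 small nuclear RNA genes fell and 5 rose; whether RNA quality differed between the groups was not tested.

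Most sterol, antioxidant and proliferation genes measured rose in the late carcinomas as well. Of the cholesterol synthesis list, 14 of 18 rose and 1 fell, both over all genes tested and adjusted over the list alone (camera adjusted p = 9.70e-08; adjusted p = 0.278 with an estimated correlation). Sqle, an oxygenase of sterol synthesis, rose by 1.27 (SE 0.185, limma adjusted p = 4.26e-04). Of the NRF2 targets, 9 of 16 rose over all genes tested, and 10 rose and 1 fell adjusted over the list alone (camera adjusted p = 9.02e-06; adjusted p = 0.252 with an estimated correlation). The glutathione transferase Gsta4 rose by 6.15 (SE 0.670, adjusted p = 8.12e-05), and the glutathione reductase Gsr rose by 2.69 (SE 0.407, adjusted p = 5.53e-04). In the cell cycle and mitosis list, 28 of 41 rose over all genes tested and 29 adjusted over the list alone, with 0 falling (camera adjusted p = 4.03e-12; adjusted p = 0.294 with an estimated correlation). The proliferation marker Mki67 rose by 1.84 (SE 0.269, adjusted p = 4.41e-04). Of the CREB and CRTC targets, 8 of 19 rose and 4 fell, over all genes tested and adjusted over the list alone (camera adjusted p = 0.0404; adjusted p = 0.252 with an estimated correlation). Without late carcinoma replicate 1, 5 members rose, and without late carcinoma replicate 2, 1 fell. The call of that list was lost in 9 settings: beside the estimated correlation, with camera on ranks (adjusted p = 0.133), the dim filter at the 30th percentile (0.0947), the 5th percentile of each array as a covariate (0.155) and early carcinoma replicate 3 and PADC replicate 2 both left out (0.0698). It was also lost after cyclic loess (0.0651) and without late carcinoma replicate 2 (0.0576), PADC replicate 1 (0.0567) or PADC replicate 2 (0.0601). Its member Sik1, a kinase of the AMPK family, rose by 1.94 (SE 0.132, adjusted p = 1.12e-05).

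Immune genes moved in different directions in the late carcinomas. Of the neutrophils and granulocyte chemoattractants list, 12 of 21 rose and 1 fell, over all genes tested and adjusted over the list alone (camera adjusted p = 2.27e-04; adjusted p = 0.356 with an estimated correlation). S100a8, a calcium-binding protein abundant in neutrophils and also made by squamous epithelium, rose by 7.40 (SE 1.07, limma adjusted p = 4.13e-04). Arg1, an arginase made by macrophages among other cells, rose by 5.36 (SE 0.582, adjusted p = 8.02e-05), while the macrophages list had 3 of 20 rising and 3 falling over all genes tested, and 3 and 4 adjusted over the list alone; 5 fell without early carcinoma replicate 3. Of the interferon response list, 18 of 24 fell and 1 rose, over all genes tested and adjusted over the list alone (camera adjusted p = 8.76e-07; adjusted p = 0.294 with an estimated correlation). Stat2, a transcription factor of the interferon pathway, fell by 1.68 (SE 0.250, adjusted p = 4.99e-04). Of the antigen presentation list, 9 of 15 fell over all genes tested and 9 adjusted over the list alone (camera adjusted p = 1.30e-04; adjusted p = 0.294 with an estimated correlation), among them H2-Q4, which fell by 1.67 (SE 0.129, adjusted p = 1.46e-05). Of the T and NK cells list, 10 of 21 fell over all genes tested and 11 adjusted over the list alone (camera adjusted p = 1.70e-04; adjusted p = 0.257 with an estimated correlation), but 3 fell after cyclic loess and 1 after quantile normalization. Of the B and plasma cells list, 5 of 16 fell and 1 rose, over all genes tested and adjusted over the list alone (camera adjusted p = 0.0172; adjusted p = 0.299 with an estimated correlation), with the antibody heavy chain Ighm down by a log2 difference of -2.96 (SE 0.580, adjusted p = 0.00289). The call of this list was lost after cyclic loess (adjusted p = 0.239), and 3 members fell without late carcinoma replicate 1.

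Some prostate secretory genes fell in the late carcinomas. Of the mouse prostate secretory genes, 9 of 20 fell over all genes tested and 13 adjusted over the list alone, with 0 rising (camera adjusted p = 9.68e-05; adjusted p = 0.309 with an estimated correlation), and 16 fell without the array labelled early carcinoma replicate 3. Sbp, the spermine-binding protein, fell by 3.83 (SE 0.494, limma adjusted p = 2.06e-04), and Sbpl fell by 3.85 (SE 0.409, adjusted p = 7.08e-05). Smooth muscle and skeletal muscle genes did not separate these groups: 1 of 18 rose and 0 fell in the first list, and 0 of 19 rose and 1 fell in the other, with 0 and 1 called adjusted over the list alone (camera adjusted p = 0.634 and 0.608; adjusted p = 0.914 for both with an estimated correlation). Without the array labelled early carcinoma replicate 3, 3 smooth muscle genes fell. Of the 45 lists, 21 passed camera between late carcinomas and PADC, 16 higher and 5 lower, 0 of them with an estimated correlation (smallest adjusted p = 0.252), and fry called 25. As in the early comparison, 1259 of the rises were pseudogenes that share sequence with their parent genes and are uncertain.

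**Figure D3:**
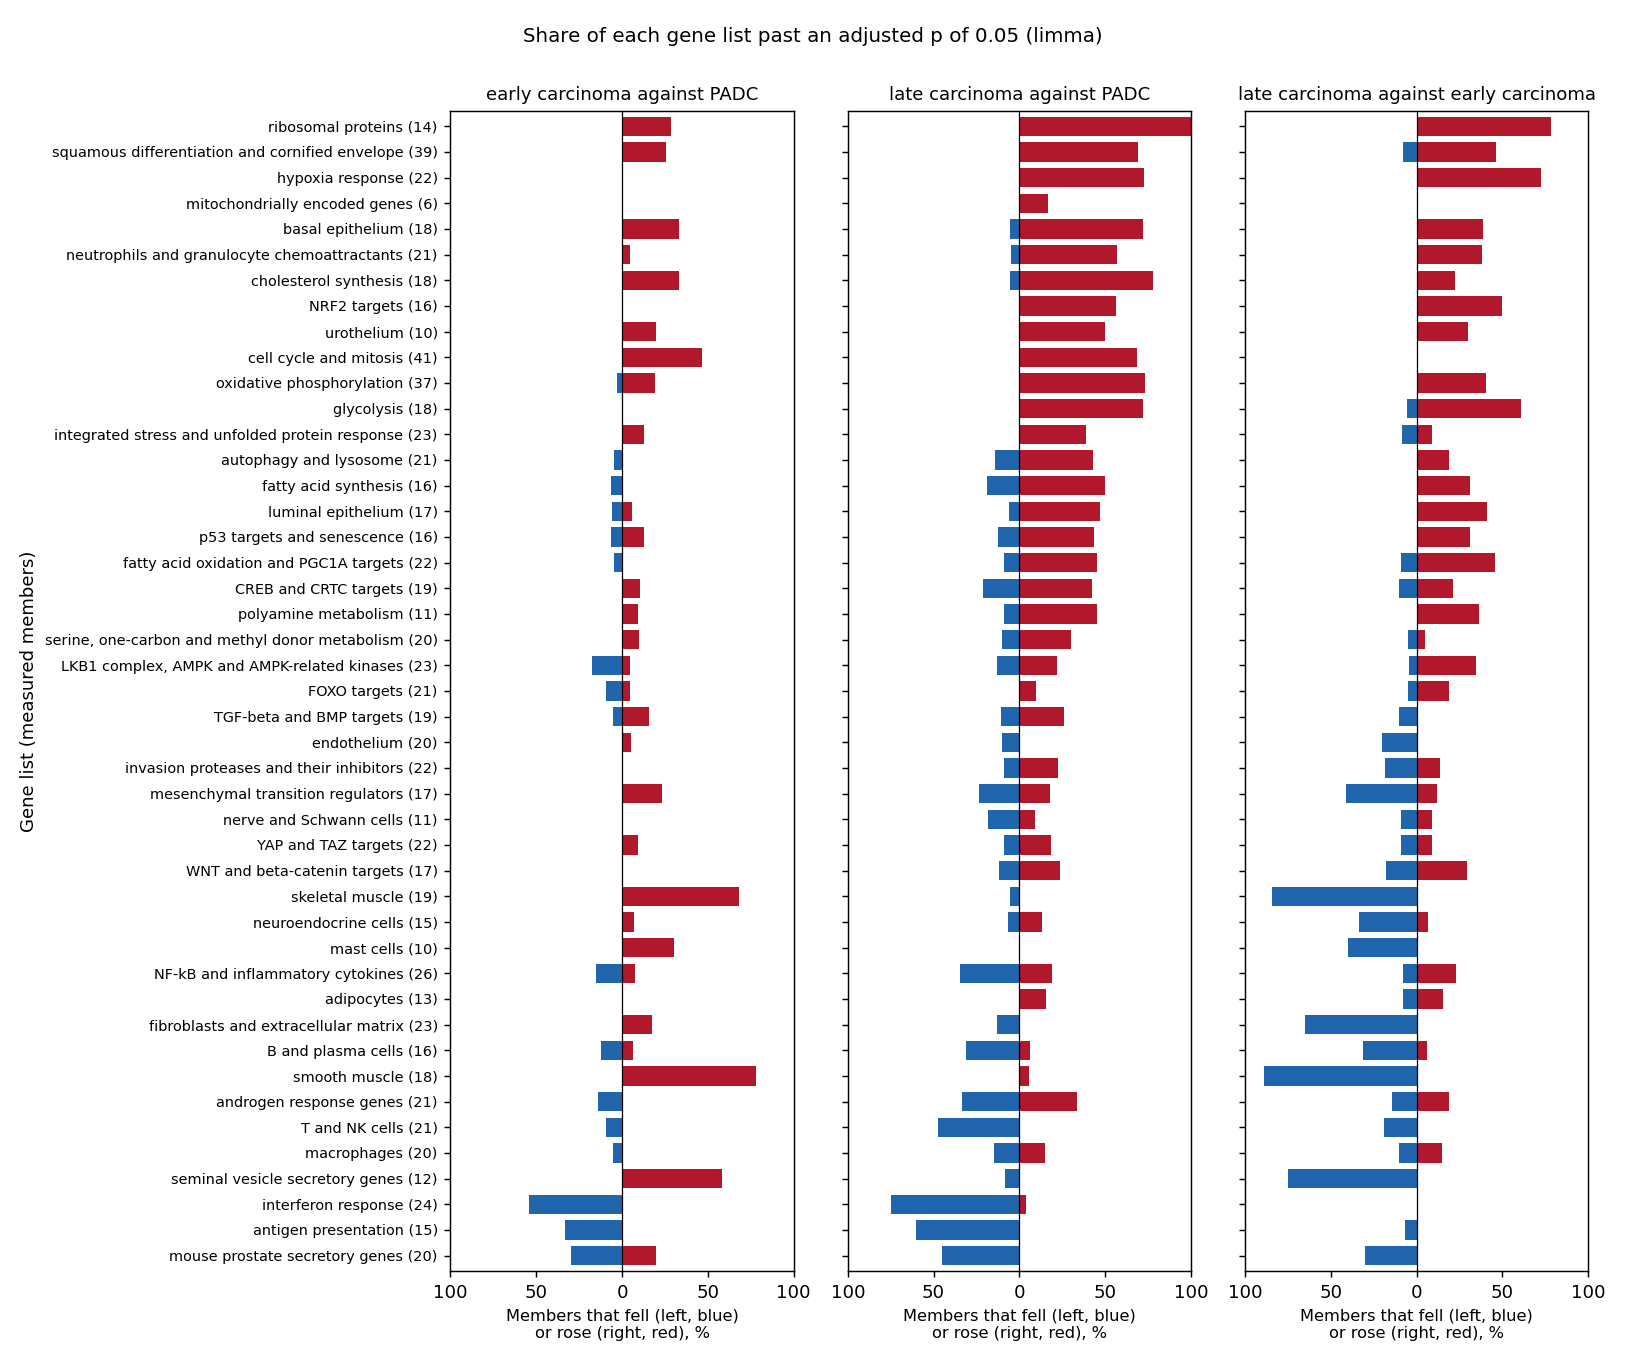
Members of each of 45 gene lists (vertical axis, with the number of measured members) that rose (red, right of 0) or fell (blue, left of 0) past an adjusted p of 0.05 in limma, as a percent of the measured members, in the 3 comparisons. The squamous list rises in 10, 27 and 18 of 39 members, and the smooth muscle list rises in 14 of 18 members in early carcinomas against PADC and falls in 16 of 18 in late against early carcinomas.

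Late and early carcinomas, whose labels give 1 genotype, were compared to follow the change with stage. Sprr2f was 17.29 ± 1.18 (SD, n = 4) in the late and 9.21 ± 2.56 (SD, n = 4) in the early carcinomas, a rise of 8.08 log2 units (SE 0.996, limma adjusted p = 8.20e-04). Sprr2d rose by 6.62 (SE 0.912, adjusted p = 0.00114), Defb14 by 5.92 (SE 0.98, adjusted p = 0.00256) and Ltf by 4.88 (SE 0.71, adjusted p = 0.00146). On the array labelled early carcinoma replicate 3 Sprr2f read 5.99 (other early arrays 8.41 to 11.8) and Ltf 12.57 (others 15.24 to 16.55). That array therefore adds to the size of these 2 rises. Several secreted proteins were lower at the late stage. Pbsn, the androgen-driven probasin, was 4.35 ± 0.36 (SD, n = 4) against 9.53 ± 3.48 (SD, n = 4), a log2 difference of -5.18 (SE 1.32, adjusted p = 0.0156). The secretoglobins Scgb1b20 and Scgb2b24 fell by 5.18 (SE 1.13, adjusted p = 0.00847) and fell by 5.14 (SE 0.826, adjusted p = 0.00228), and Tgm4 fell by 5.06 (SE 1.20, adjusted p = 0.0120). The array labelled early carcinoma replicate 3 held the highest Pbsn of all 13 arrays, at 14.68. Without it the log2 differences were -3.47 for Pbsn, -3.76 for Scgb1b20, -3.97 for Scgb2b24 and -3.41 for Tgm4. Scgb2b24 (3.02) and Tgm4 (3.68) lay below olfactory receptor genes (4.13) in the late carcinomas, so the sizes of their falls are uncertain. Of the mouse prostate secretory genes, 6 of 20 fell and 0 rose, over all genes tested and adjusted over the list alone (camera adjusted p = 0.0444; adjusted p = 0.585 with an estimated correlation). The call of this list was lost without early carcinoma replicate 3 (adjusted p = 0.0684), late carcinoma replicate 1 (0.0625), late carcinoma replicate 2 (0.0523), late carcinoma replicate 3 (0.0630) or PADC replicate 2 (0.0542), without early carcinoma replicate 3 and PADC replicate 2 together (0.0843), with array weights (0.107) and with fry (0.0570).

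Of 30176 genes, 3183 rose and 4984 fell from the early to the late stage (limma, Benjamini-Hochberg), and 894 of the rises and 262 of the falls were 2-fold or more on the deposited scale. This split turned with the scaling: 39.0% of the 8167 calls were rises, against 51.8% of 4328 after cyclic loess, 55.7% of 3619 after quantile normalization and 78.4% of 7241 with each array centred on its median. The median over all genes was -0.08 as deposited and 0.07 after centring, so a log2 difference of about that size between the stages has no settled direction. Calls numbered 4766 and 4686 without early carcinoma replicates 1 and 2, and 5432 and 4944 without late carcinoma replicates 1 and 2. Among the 10055 dimmest genes 53 rose and 2424 fell, and among the 10060 brightest 2802 rose and 597 fell.

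Most hypoxia genes measured, and some squamous genes, rose with stage. Of the hypoxia response list, 16 of 22 rose over all genes tested and 18 adjusted over the list alone, with 0 falling (camera adjusted p = 7.70e-12; adjusted p = 0.212 with an estimated correlation). Egln3, an oxygen-sensing hydroxylase, rose by 3.28 (SE 0.519, limma adjusted p = 0.00210), and Ero1a rose by 2.16 (SE 0.330, adjusted p = 0.00179). Of the glycolysis list, 11 of 18 rose and 1 fell over all genes tested, and 13 rose and 1 fell adjusted over the list alone (camera adjusted p = 7.45e-08; adjusted p = 0.212 with an estimated correlation). Ldha, the muscle-type lactate dehydrogenase subunit, rose by 1.16 (SE 0.170, adjusted p = 0.00153). In the list of squamous differentiation and cornified envelope genes, 18 of 39 rose and 3 fell over all genes tested, and 19 rose and 3 fell adjusted over the list alone (camera adjusted p = 1.04e-06; adjusted p = 0.324 with an estimated correlation). Of the basal epithelium list, 7 of 18 rose over all genes tested and 7 adjusted over the list alone (camera adjusted p = 5.06e-05; adjusted p = 0.304 with an estimated correlation), with Krt5 up by 3.68 (SE 0.625, adjusted p = 0.00287) and Trp63 by 1.16 (SE 0.205, adjusted p = 0.00340). The number of squamous genes that rose was 12 without late carcinoma replicate 2, and that of basal genes was 3.

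Most muscle, matrix and seminal vesicle genes measured were lower at the late stage. In the smooth muscle list 16 of 18 fell over all genes tested and 16 adjusted over the list alone, with 0 rising (camera adjusted p = 6.59e-07; adjusted p = 0.212 with an estimated correlation). Tagln fell by 1.73 (SE 0.272, limma adjusted p = 0.00208). In the skeletal muscle list 16 of 19 fell over all genes tested and 17 adjusted over the list alone (camera adjusted p = 7.45e-08; adjusted p = 0.212 with an estimated correlation), and Ttn fell by 1.93 (SE 0.260, adjusted p = 0.00109); its late mean (4.09) lay below that of olfactory receptor genes (4.13), so the size is uncertain. Of the fibroblasts and extracellular matrix list, 15 of 23 fell over all genes tested and 19 adjusted over the list alone (camera adjusted p = 2.09e-05; adjusted p = 0.324 with an estimated correlation), but 10 fell after cyclic loess, 8 after quantile normalization and 7 without late carcinoma replicate 3. Postn fell by 1.94 (SE 0.424, adjusted p = 0.00861; -2.44 and 0.0520 with the 5th percentile of each array as a covariate), and the matrix proteoglycan Lum fell by 2.10 (SE 0.476, adjusted p = 0.0101). Of the seminal vesicle secretory genes, 9 of 12 fell over all genes tested and 9 adjusted over the list alone (camera adjusted p = 2.39e-05; adjusted p = 0.212 with an estimated correlation), and Sva fell by 3.06 (SE 0.422, adjusted p = 0.00114); its late mean (3.06) lay below that of olfactory receptor genes (4.13), so the size is uncertain.

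The remaining groups of the stage comparison were mixed. Of the NRF2 targets, 8 of 16 rose over all genes tested and 9 adjusted over the list alone (camera adjusted p = 8.00e-06; adjusted p = 0.212 with an estimated correlation), with Gsta4 up by 4.17 (SE 0.706, limma adjusted p = 0.00286), but 4 rose after cyclic loess, 2 after quantile normalization and 5 without early carcinoma replicate 1. Of the oxidative phosphorylation list, 15 of 37 rose over all genes tested and 15 adjusted over the list alone (camera adjusted p = 2.15e-08; adjusted p = 0.320 with an estimated correlation), but 4 rose and 1 fell after cyclic loess and 5 rose without early carcinoma replicate 1, and the call was lost with the 5th percentile of each array as a covariate (adjusted p = 0.267). Ribosomal proteins rose in 11 of 14 members over all genes tested and 12 adjusted over the list alone (camera adjusted p = 9.17e-08, and 0.212 with an estimated correlation), but in 3 after cyclic loess and in 5 without late carcinoma replicate 1. Small nuclear RNA genes fell in 260 of 915 and rose in 8, while of 62 ribosomal RNA genes 0 rose and 0 fell. Whether RNA quality differed between the stages was not tested. Of the neutrophils and granulocyte chemoattractants list, 8 of 21 rose over all genes tested and 8 adjusted over the list alone (camera adjusted p = 1.02e-04; adjusted p = 0.326 with an estimated correlation), with the chemokine Cxcl5 up by 1.91 (SE 0.392, adjusted p = 0.00664), and 5 rose without late carcinoma replicate 4. Sik1 rose by 1.57 (SE 0.140, adjusted p = 2.97e-04). The cell cycle and mitosis list had 0 of 41 members past the threshold in either direction and the interferon response list 0 of 24; without the array labelled early carcinoma replicate 3, 3 cell cycle genes fell and 1 interferon gene rose, and without early carcinoma replicate 4, 2 cell cycle genes rose. Of the 45 lists, 24 passed camera, 18 higher and 6 lower, 0 of them with an estimated correlation (smallest adjusted p = 0.212), and fry called 25.

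The differences of the early and the late carcinomas from PADC were correlated across genes (r = 0.666, covariance 0.173), where genes are not independent replicates. Both comparisons use the same 5 PADC arrays: groups simulated without change against shared controls gave a mean r of 0.444 and a covariance of 0.0138 over 100 simulations. Resampling the residuals of whole arrays, which keeps the correlation between genes, gave a mean r of 0.462 with a range of -0.347 to 0.984 over 100 draws. The mean covariance was 0.0158. Arrays were drawn with replacement, so the same array could stand in more than 1 group, which may widen this range. By this resampling r alone cannot be said to separate the data from unchanged groups. With different PADC arrays for each stage, r ran from 0.392 to 0.692 (median 0.601) and the covariance from 0.119 to 0.188 over 20 assignments. In total 969 genes rose in both comparisons, 633 fell in both and 63 moved in opposite directions. With different PADC arrays for each stage, and so fewer arrays in each comparison, 73 to 860 rose in both and 62 to 363 fell in both.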

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

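A sample far from the others of its group was flagged in 23 of 324 groups of values of the named genes, where chance flags 1 in 20 groups, or 16.2. On the array labelled early carcinoma replicate 3 the values far above the group were Scgb2b24 (11.66, others 6.86 to 7.17), Sva (7.88, others 5.46 to 5.63), Svs6 (7.93, others 5.44 to 5.85), Scgb2b10 (11.09, others 7.51 to 7.99) and Cpa3 (5.32, others 4.43 to 4.52). In the other early carcinomas Ighm was low in replicate 1 (5.49, others 6.62 to 6.70), Sbp was low in replicate 4 (5.45, others 5.93 to 6.02) and Psca was high in replicate 4 (10.72, others 9.40 to 9.55). In the late carcinomas Gsdmc3 (8.87, others 7.32 to 7.56), Gsdmc4 (7.55, others 6.76 to 6.83) and Cma1 (4.83, others 4.67 to 4.69) were high and Cpa3 (3.67, others 3.81 to 3.83) was low in replicate 2. Ltf (20.16, others 19.80 to 19.82) and Sik1 (9.72, others 9.40 to 9.41) were high in replicate 1, H2-Q4 (6.94, others 6.50 to 6.53) and Slc12a2 (8.2, others 6.52 to 6.74) in replicate 3, and Sva (3.15, others 3.02 to 3.03) and Sbp (5.84, others 4.91 to 5.02) in replicate 4. In PADC Ltf (13.26, others 10.92 to 11.54) and Svs5 (11.15, others 3.71 to 5.55) were high and Dusp1 (4.8, others 5.55 to 5.76) was low in replicate 5, and Sprr2d (5.33, others 6.14 to 6.44) was low and Cald1 (7.08, others 6.45 to 6.61) was high in replicate 3.

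A difference between groups was flagged for 8167 genes, whose difference from PADC differed between the early and the late carcinomas; the shared PADC arrays cancel, so this is the limma test of late against early carcinomas. A signal outside the genes tested was flagged in the 35318 probe sets without 1 gene symbol: 1848 were higher and 859 lower in the early carcinomas than in PADC, and 1457 were higher and 2937 lower in the late carcinomas. Of the higher ones, 312 and 716 were 2-fold or more on the deposited scale.

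The test of a wrong label was chosen after the result was seen, and it replaced a first axis from late carcinomas (0) to PADC (1), on which this array lay at 0.660 and the other early arrays between 0.402 and 0.660; the tests of range and tissue content had predictions written before they were run. Along the genes that separate the other early carcinomas from PADC, 0 is the mean of the other early arrays. The array labelled early carcinoma replicate 3 lay at 0.385 and the PADC arrays between 0.842 and 1.07. The PADC arrays helped to choose these genes and this array did not, so the test cannot exclude a wrong label. This array lay inside the PADC range in Stk11 (7.21, PADC 7.18 to 7.39) and in the squamous (5.62, PADC 5.50 to 5.72), basal (6.48, PADC 6.34 to 6.64) and endothelium means. It lay above that range in the secretory (8.32, PADC at most 7.91), smooth muscle (6.98, PADC at most 5.43) and fibroblast means (6.89, PADC at most 6.52). Its range between the 5th and the 95th percentile, 5.37, was the widest of the early arrays, so a narrow signal range was excluded. Its 5th percentile, 3.76, was the lowest of the early arrays (others 3.92 to 3.97), and whether its background level sets it apart was not tested. More non-malignant prostate tissue in the piece predicted that the secretory, smooth muscle, fibroblast and endothelium lists would all be higher: the secretory (8.32, others at most 6.64) and smooth muscle means (6.98, others at most 6.20) were, the fibroblast mean (6.89, others 6.77 to 7.01) was not, and the endothelium mean (5.25, others 5.32 to 5.43) lay below the others. A list below the others was set beforehand as the mark against this explanation, and the endothelium list met it. The endothelium shortfall was smaller than the range of the other arrays, a condition that was not set beforehand. With that condition the test cannot tell, and no biological explanation was tested.

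The test on olfactory receptor genes was chosen after the result was seen. These 1082 genes, which prostate tissue is not known to express widely, were higher in the early than in the late carcinomas by a median of 0.24 log2 units. Not every early array was higher: their mean was 4.41 to 4.49 on early carcinoma replicates 1, 2 and 4 but 4.17 on replicate 3. The late arrays read 4.10 to 4.16. In PADC replicates 2 and 3 read 4.41 and 4.36, and the other PADC arrays 4.18 to 4.27. After cyclic loess the late minus early median was -0.07, and the share called fell from 23.6% to 10.4%. A difference in background level between the arrays could therefore account for part of the 2424 falls among the dimmest genes, and the test cannot tell it from biology.

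The wider signal range of the late arrays was tested against random lists of the same mean expression, 10000 for each list. The median of the ribosomal protein list in late carcinomas against PADC lay at the percentile 98.1, short of the limit set for excluding the range, so the test cannot tell. The oxidative phosphorylation list lay at 99.94 (median 0.54, highest random list 0.60) and the hypoxia response list at 100 (median 1.0, highest random list 0.57). For them the range alone rarely or never gave such a median in lists of unrelated genes. The random genes were drawn independently, whereas genes of a list can move together, so these percentiles may be too high and the range is not excluded outright. The glycolysis list lay at 99.72, short of the same limit, so for it the range stays open.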

How the results depend on the processing

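Counts of called genes depended on the processing. For early carcinoma against PADC, 3167 genes became 5353 with all probe sets, 6871 with array weights, 1534 with only the groups compared, 639 with a plain two-sample test, 628 at 2-fold, 6090 with early carcinoma replicate 3 and PADC replicate 2 both left out and 1909 with protein-coding genes only, and ranged from 1529 to 6405 leaving out each array. For late carcinoma against PADC, 7766 became 2040 at 2-fold and ranged from 5516 to 8868. For late against early carcinoma, 8167 became 4328 after cyclic loess, 3619 after quantile normalization, 4638 with the dim filter at the median, 13390 with all probe sets, 1610 with the 5th percentile of each array as a covariate, 3049 with a plain two-sample test and 1156 at 2-fold, and ranged from 4686 to 10986. With all probe sets, the dim filter or protein-coding genes only, the number of units tested changed. The single fit shares 1 spread per gene over the 3 groups. Early arrays correlated less with each other (r 0.968 to 0.985) than late arrays (0.989 to 0.992). Its p-values may therefore be too small for early carcinoma against PADC and too large for late carcinoma against PADC. The latter gave 8304 genes with only the groups compared. How far this accounts for the other changes in counts was not tested. Lists passing camera numbered 0 in each comparison with an estimated correlation, and ranged from 16 to 20, 20 to 24 and 22 to 25 leaving out each array. Stk11 in late against early carcinoma reversed to 0.03 with centred arrays and to 0.046 without early carcinoma replicate 3, alone or with PADC replicate 2, in a range of -0.22 to 0.046. For early carcinoma against PADC its call was lost with only the groups compared (adjusted p = 0.0585). With the covariate camera's direction reversed for 4 list results, with these medians: luminal epithelium in early carcinoma against PADC (-0.030, the same sign as before) and in late against early carcinoma (-0.20), and FOXO targets (-0.10) and fatty acid synthesis (0.025, the same sign as before) in late against early carcinoma. Of 4174 values of named genes under alternatives, 4048 kept direction and call, 114 lost the call, 9 gained it and 3 reversed. Of 1364 values of lists, 1219 kept both, 141 lost the call and 4 reversed. The named genes were picked by large change or small p, and the lists by passing camera, on these same arrays. The shares that kept their call therefore do not measure how stable other genes or lists are. The replicate block gave 1171 genes for early carcinoma against PADC and 4964 for late against early carcinoma, and with it the calls of Krt5, Tgm4 and Acta2 in early carcinoma against PADC were lost (adjusted p = 0.0668, 0.0712 and 0.0505). Among 12 pairs of arrays with the same number r ran from -0.514 to 0.422, and 2 correlated best with their own number. No pairing was seen, but so few pairs cannot exclude one. The covariate, leaving out both arrays together and protein-coding genes only were added after the data were seen. Stk11 is on 1 probe set, so the alternative of every probe set gave no other value, and Pten was not analysed. No measured background level was at hand, so the sizes of changes that start or end among dim genes are uncertain.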

Other observations

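In late against early carcinomas, 7 of 17 luminal epithelium genes rose over all genes tested and 7 adjusted over the list alone (camera adjusted p = 8.72e-04; adjusted p = 0.378 with an estimated correlation). With the 5th percentile of each array as a covariate its direction turned (median -0.20), and after cyclic loess its call was lost (adjusted p = 0.440). Elf3, an epithelial transcription factor, rose by 1.98 log2 units (SE 0.268, limma adjusted p = 0.00109), and the tight junction gene Cldn4 rose by 2.34 (SE 0.380, adjusted p = 0.00239; 1.23 and 0.108 with that covariate). Of the LKB1 complex, AMPK and AMPK-related kinases, 8 of 23 rose and 1 fell over all genes tested, and 10 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.00229; adjusted p = 0.212 with an estimated correlation). Its call was lost after cyclic loess (adjusted p = 0.164) and with the covariate (0.380). Of the mesenchymal transition regulators, 2 of 17 rose and 7 fell over all genes tested and adjusted over the list alone (camera adjusted p = 0.393; adjusted p = 0.764 with an estimated correlation), with S100a4 down by a log2 difference of -0.91 (SE 0.113, adjusted p = 8.49e-04) and Zeb1, a repressor of epithelial genes, by -0.54 (SE 0.110, adjusted p = 0.00638). Without early carcinoma replicate 2, 1 member of that list rose and 3 fell. In the mast cell list 4 of 10 fell over all genes tested and 4 adjusted over the list alone (camera adjusted p = 0.107; adjusted p = 0.304 with an estimated correlation), among them the chymase Cma1 with -0.63 (SE 0.102, adjusted p = 0.00243).

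The hypothesis that the counts arise from any grouping of the arrays was tested by regrouping arrays across the groups. The count of genes was the highest of 100 splits for early carcinoma against PADC (rank 1; 3167, highest other 1865), of 100 splits for late carcinoma against PADC (rank 1; 7766, highest other 3301) and of 35 splits for late against early carcinoma (rank 1; 8167, highest other 16). The number of lists passing camera was reached or exceeded in 26 of 100 splits (17, highest other 24), 18 of 100 splits (21, highest other 25) and 3 of 35 splits (24, highest other 25), the real grouping included. In the other splits a median of 14, 16 and 14.5 lists passed. No other split drawn gave as many genes as the real grouping, whereas other splits gave as many lists. In early carcinoma against PADC, the split with 1865 genes set early carcinoma replicate 3 and PADC replicates 1, 4 and 5 against the rest. The 5th percentiles of those arrays were 3.76 to 3.79, and those of the rest were 3.88 to 3.97. A difference in background level between arrays could therefore account for part of the gene counts, and regrouping cannot exclude it.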
